A study of Macaca mulatta with 25 samples.

How the data were processed

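The samples were cervix from 25 ovariectomized rhesus macaques in artificial hormone cycles, in 5 groups of 5 animals according to the labels, with 1 array each. The series' design text gives other group sizes, 13, 4, 5, 5 and 10 animals from E2 to E+14P, and the groups used here follow the labels of the arrays. Per the labels, total RNA was extracted from frozen tissue, amplified with a whole-transcript kit, labelled with biotin and read on an Affymetrix whole-transcript rhesus gene array.

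The deposited table holds log2 signals, with 40489 probe sets and 25 arrays and no missing value. The submitters' processing notes name Affymetrix Expression Console; its version, the summarization and the normalization are not given in the sources used here. The log2 unit was read from the range of the values, 0.618 to 13.69. Sorted values of the arrays differed from their common mean by at most 0.29, so the arrays had been normalized to nearly the same distribution. No background values or detection calls were used here, so signal over background is unknown per probe set.

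Of the probe sets, 16020 were listed for a gene with 1 symbol, 490 for several and 23979 for none. No probe set was marked as an array control, so all were tested. A gene was represented by its probe set with the highest mean over all arrays, which gave 15534 genes, 418 of them with more than 1 probe set. Genome positions were not given in the sources used here.

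Differences were tested with limma 3.58.1 in R 4.3.3. The fit had 1 coefficient per group and used all 25 arrays, which left 20 residual degrees of freedom. Variances were moderated with a mean trend (median prior degrees of freedom 3.09). The p values rest on a spread between animals that is pooled over the 5 groups. For a group whose animals vary more than the others, this pooled spread is too small. The p values were adjusted by Benjamini and Hochberg over the 40489 probe sets, with a threshold of 0.05, and tests were 2-sided. There were 4 comparisons with E2, 3 of consecutive times and an F test over the 4 comparisons with E2. Each change is a log2 fold change, the later or treated group minus the other, with its standard error.

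Fixed before the data were examined were the groups, the tests, 27 gene lists, the rule for named genes and most alternatives. The lists held 701 entries, of which 569 were measured. They covered estrogen and progestin responses, mucins, ion and water transport, cell cycle, ciliated, squamous and columnar epithelium, collagens, matrix remodelling, prostaglandins, smooth muscle, endothelium, T and natural killer, B and plasma, myeloid, neutrophil and mast cells, cytokines, epithelial defence, interferon response, cell junctions, endoplasmic reticulum folding and secretion, immediate early genes, blood, fat with nerve and skeletal muscle, and endometrium. Several lists share members, and the cervix expresses many of them in more than 1 cell type. Lists were tested with camera in limma on 1 probe set per gene, with a preset correlation of 0.01 and Benjamini and Hochberg adjustment over the lists of a comparison. An estimated correlation served as an alternative. Members called were counted from the adjustment over all probe sets and also adjusted over the list alone.

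Named genes were, for each comparison with E2, the 8 highest and 8 lowest changes among called genes whose mean in the higher group reached the median of all probe sets, and 4 of each for consecutive times. Where fewer than 5 genes were called, the 5 with the lowest p were taken. PGR, ESR1 and FKBP5 and up to 4 members per list were added. The rule gave 149 genes, 80 of which are given in the text. The others were left out for length. For 0 of these genes did another probe set of the gene have a call in the opposite direction. Another 12 genes, in the closing part, were chosen after their values were seen.

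Tissue makeup was described by the mean log2 signal of the squamous, columnar, ciliated and smooth muscle lists on each array. Arrays over 4 scaled median absolute deviations from the median of all arrays in the squamous, columnar or ciliated list are said to stand apart. There were 4, E+3P replicates 2 and 3 and E+14P replicates 4 and 5.

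The alternatives were quantile normalization, centring of arrays on their median, leaving out probe sets under the 40th percentile of mean signal, no variance trend, array weights, a fit of the compared groups alone, 1 probe set per gene, a minimum change of 1.5-fold, a squamous or a smooth muscle covariate, an estimated correlation and leaving out each array in turn. Leaving out the arrays that stand apart, 3 makeup covariates together and leaving out the first 2319 unnamed rows, which may be array controls, were chosen after seeing the data. The 3 makeup covariates were the squamous, columnar and smooth muscle means of each array, without the ciliated mean. A list fitted with its own mean as a covariate loses its average shift by construction, so such a fit decides nothing about that list. Other pseudocounts were not run because the table was already on the log2 scale. Replicate numbers follow the order of the deposit, so no pairing was used.

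The procedure was tested on simulated data, 25 arrays with the means and spreads of the 40489 probe sets and with changes put into the E+7P arrays. Compared with E2, it recovered 75 of 100 probe sets given a log2 change of 1 and 97 of 100 given a change of 2, and called 13 others. A list shifted by 0.5 was called and 0 other lists were. The simulated probe sets were drawn independently, so the genes of a list were not correlated. In the real data the estimated correlation reached 0.877 for smooth muscle genes. The simulation therefore cannot show how often the preset correlation gives false list calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.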

Results

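Gene expression was measured with a whole-transcript rhesus gene array in the cervix of 25 ovariectomized rhesus macaques, which were given artificial menstrual cycles with implants that release estradiol and progesterone. Each of the 5 groups held 5 animals, with 1 array per animal. The E2 group had received estradiol alone for 14 days. In the other groups progesterone had been added for 1 day (E+1P), 3 days (E+3P), 7 days (E+7P) or 14 days (E+14P). The labels do not give the days of estradiol in these groups. If estradiol lasted longer in them than in E2, its effect cannot be separated from that of progesterone. Each array gave log2 signals for 40489 probe sets, of which 16020 were listed for a gene with 1 symbol. The array medians lay between 5.502 and 5.604 on the log2 scale, and the number of arrays limits the precision of each comparison. Genome positions were not given in the sources used here, so genes are named by symbol and, for some, by probe set.

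**Figure D1:**
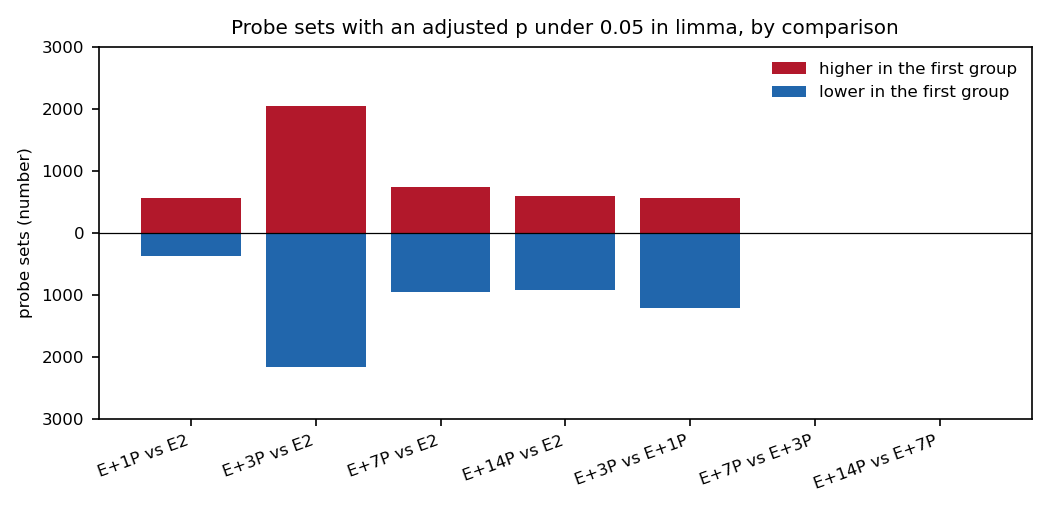
The bars show the number of probe sets that passed limma's test in each comparison, higher above 0 and lower below 0. The comparison of E+3P with E2 has 2051 higher and 2163 lower probe sets, and the comparison of E+14P with E+7P has 0.

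The comparison of E+1P with E2 asks what a day of progesterone changes in a cervix prepared with estradiol. FKBP5 (probe set 13745816), a co-chaperone of steroid receptors and a known progestin target, rose from a log2 signal of 5.67 ± 0.36 to 8.06 ± 0.11 (mean ± SD, n = 5 per group), and all 5 E+1P arrays lay above every E2 array. Its log2 fold change was 2.39 (SE 0.21, adjusted p = 1.99e-06). The receptor genes for both hormones fell, PGR from 10.75 ± 0.19 to 9.65 ± 0.24 (adjusted p = 0.00295) and ESR1 from 8.95 ± 0.32 to 8.03 ± 0.14 (adjusted p = 0.014), with all 5 E+1P arrays below every E2 array for both genes. SCGB1D4, a secretoglobin gene, rose by 3.48 (SE 0.67, adjusted p = 0.00434) from a low E2 signal of 2.70 ± 0.36. KRT222, a keratin family gene, rose by 2.84 (SE 0.31, adjusted p = 1.22e-05), and RGCC, a regulator of the cell cycle, rose by 2.56 (adjusted p = 0.000735). MME, which encodes the membrane peptidase neprilysin, rose by 2.47 (adjusted p = 0.0004), ALDH1A3, an enzyme of retinoic acid synthesis, by 2.46 (adjusted p = 0.000141), and HGD, an enzyme of tyrosine breakdown, by 2.31 (adjusted p = 6.84e-06). The probe set listed for MIR147B rose by 1.99 (adjusted p = 0.00876); the listing is for a microRNA locus, and which transcript the probe set measures is not settled by the annotation.

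Genes that fell after 1 day included SEMA3D, a secreted guidance molecule, by 2.80 (SE 0.46, adjusted p = 0.00098), while DIO2, the deiodinase that activates thyroid hormone, fell by 2.44 (SE 0.32, adjusted p = 9.34e-05). The glutamate receptor subunit gene GRIA2 dropped by 2.34 (adjusted p = 0.000445) and the cadherin gene CDH12 by 2.32 (SE 0.25, adjusted p = 9.64e-06). The alarmin gene IL33 decreased by 2.09 (SE 0.41, adjusted p = 0.00555), and the proteoglycan gene VCAN by 2.03 (SE 0.45, adjusted p = 0.0143). MUC15, a membrane mucin, rose by 2.69 (adjusted p = 0.0298), and the transcriptional regulator gene CITED1 fell by 2.43 (adjusted p = 0.0259), with less margin. Without E+1P replicate 1, 3 or 4 or E2 replicate 1, 2 or 4 the MUC15 call was lost (highest adjusted p = 0.0915), and the same arrays and E2 replicate 5 decided the CITED1 call (highest adjusted p = 0.0794). The CITED1 signal of E2 replicate 3 lay at the E+1P level, so that 0 of 5 E+1P arrays lay below every E2 array for this gene, and a fit of E+1P and E2 alone did not call it (adjusted p = 0.112).

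Across the fixed lists, endoplasmic reticulum folding and secretion genes were the only list with a called shift after 1 day. Of its 27 measured members 7 fell and 0 rose (16 and 0 when adjusted over the list alone), with a median log2 fold change of -0.42 and a camera adjusted p of 4.01e-09, against an adjusted p of 0.249 with an estimated correlation. PDIA6, a protein disulfide isomerase, fell by 0.62 (adjusted p = 0.00745, and 0.056 in a fit of E+1P and E2 alone). The co-chaperone gene DNAJC3 fell by 0.46 (adjusted p = 0.0336) and the ER stress protein gene MANF by 0.75 (adjusted p = 0.0259), and leaving out E+1P replicate 1 or 4 or E2 replicate 3 ended the MANF call (highest adjusted p = 0.0681). These arrays, E+1P replicate 5 and E2 replicates 4 and 5 each ended the DNAJC3 call (highest adjusted p = 0.108), and with 3 makeup covariates neither MANF (0.074) nor DNAJC3 (0.0916) was called. Of 15 immediate early genes 3 rose, BTG2 by 1.56 (adjusted p = 4.35e-05), JUN by 1.37 (adjusted p = 0.00141) and DUSP1 by 1.06 (adjusted p = 0.00583), while the list as a whole was not called (adjusted p = 0.228). Among 26 progestin response genes 3 rose and 1 fell (5 and 1 over the list alone), among them TSC22D3, a glucocorticoid and progestin target, by 1.03 (adjusted p = 0.000423). In the estrogen response list PGR and ESR1 were the 2 of 18 members that fell, and over the list alone 3 were higher and 6 lower. Mucin and mucus genes had 2 higher members of 24, MUC15 and the mucin glycosyltransferase gene ST6GALNAC1 (2.25, adjusted p = 0.0253), the latter lost without E+1P replicate 1, 3, 4 or 5 or E2 replicate 2 or 3 (highest adjusted p = 0.0678). The remaining lists had camera adjusted p values between 0.0564 and 0.963.

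In limma, 938 probe sets differed between E+1P and E2, 562 higher and 376 lower, and 309 of them by at least 2-fold (215 higher, 94 lower). They belonged to 552 genes with 1 symbol, 324 higher and 228 lower. Leaving out each of the 10 arrays in turn gave 633 to 965 probe sets, and without the 4 arrays that stand apart in tissue makeup, none of them in these groups, the shared spread gave 1322. Array weights gave 1986.

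**Figure D2:**
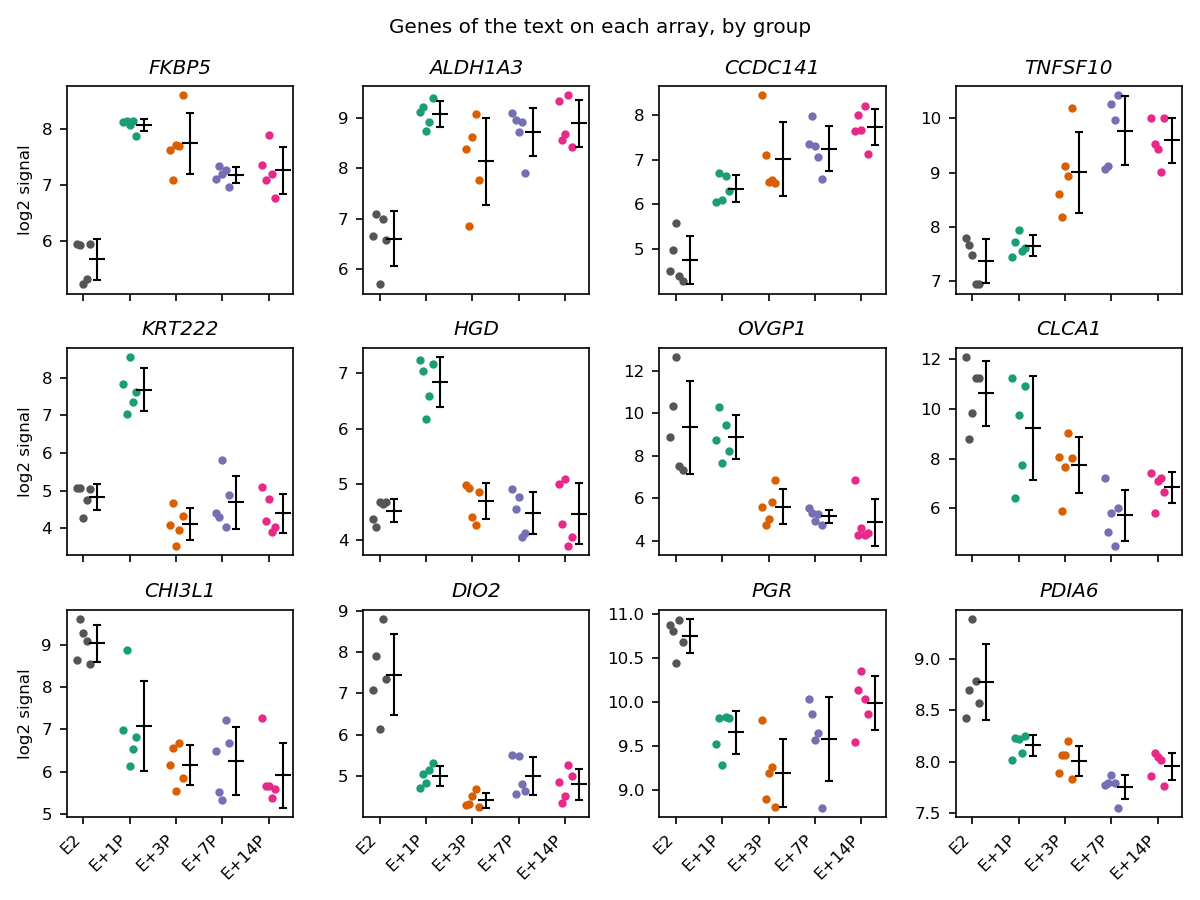
Log2 signals of 12 genes on each array are plotted by group, each point being an animal, with the mean and SD (n = 5) beside the points. FKBP5 is higher in the groups with progesterone than in E2, KRT222 and HGD are high on the E+1P arrays, and OVGP1 and CLCA1 are lower on the E+7P and E+14P arrays than on the E2 arrays.

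The comparison of E+3P with E2 asks the same question after 3 days. OVGP1, the oviductal glycoprotein and an estrogen response gene, fell from 9.33 ± 2.20 to 5.60 ± 0.82 (n = 5 per group), a change of -3.73 (SE 0.74, adjusted p = 0.00374). AGR2, a disulfide isomerase needed for mucin folding, dropped by 3.22 (SE 0.58, adjusted p = 0.00203), and the tight junction gene CLDN10 by 3.07 (SE 0.47, adjusted p = 0.000459). The chitinase-like protein gene CHI3L1 dropped by 2.87 (SE 0.44, adjusted p = 0.000454), DIO2 by 3.04 (SE 0.32, adjusted p = 1.48e-05) and SYT10, a synaptotagmin gene, by 2.94 (adjusted p = 0.00881). The Wnt inhibitor gene DKK2 decreased by 2.83 (adjusted p = 0.00754). CLCA1, a protein secreted with mucus, decreased by 2.90 (adjusted p = 0.0222), a call lost without E+3P replicate 2 or E2 replicate 1 or 5 (highest adjusted p = 0.0685), with array weights (0.0656), with the smooth muscle covariate (0.0828), without the arrays that stand apart (0.154) and with 3 makeup covariates (0.181). With 3 makeup covariates the SYT10 change was -1.49 and not called (adjusted p = 0.0619), and that of AGR2 was -1.77 and still called. In a fit of E+3P and E2 alone OVGP1 (adjusted p = 0.0609), AGR2 (0.0689), SYT10 (0.0786), DKK2 (0.072) and CLCA1 (0.0545) were not called, while CLDN10, CHI3L1 and DIO2 were.

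Higher after 3 days were GPX3, a secreted glutathione peroxidase, by 2.35 (SE 0.42, adjusted p = 0.00176), and CCDC141 by 2.26 (SE 0.33, adjusted p = 0.00026). PDK4, a brake on pyruvate oxidation, rose by 2.19 (adjusted p = 0.0118), AOX1, aldehyde oxidase, by 2.09 (adjusted p = 0.00218), and the titin gene TTN by 1.81 (adjusted p = 0.00407). QRFPR, a neuropeptide receptor gene, was 2.30 higher (adjusted p = 0.0127), with 3 of 5 E+3P arrays above every E2 array. FKBP5 remained 2.06 higher than in E2 (SE 0.21, adjusted p = 1.48e-05), and TNFSF10, which encodes the death ligand TRAIL, was 1.64 higher (SE 0.31, adjusted p = 0.00254). The potassium channel gene KCNMA1 rose by 1.89 (adjusted p = 0.0207), but not in the test without E+3P replicate 1 or 2 or E2 replicate 2 (highest adjusted p = 0.059) or without the arrays that stand apart (0.0624). In a fit of E+3P and E2 alone QRFPR (adjusted p = 0.116) and KCNMA1 (0.0545) were not called.

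Endoplasmic reticulum folding and secretion genes were lower as a group after 3 days. Of 27 members 19 fell and 0 rose (21 and 0 over the list alone), with a median of -0.61, and the call held with an estimated correlation (camera adjusted p = 9.95e-16 and 0.0275). SEC61B, a subunit of the protein channel into the endoplasmic reticulum, fell by 0.75 (adjusted p = 0.00218, and 0.0599 in a fit of E+3P and E2 alone), MANF by 1.17 (adjusted p = 0.00046) and DNAJC3 by 0.88 (adjusted p = 0.000131). Estrogen response genes were also lower, 8 of 18 called and 0 higher (10 and 3 adjusted over the list alone), with a median of -0.77 (adjusted p = 0.00203, and 0.0275 with an estimated correlation). PGR fell by 1.56 (adjusted p = 0.000108) and NRIP1, a nuclear receptor corepressor, by 1.02 (adjusted p = 0.000503), while ESR1 changed by -0.79 (adjusted p = 0.0177). The ESR1 call was lost without E+3P replicate 2 (adjusted p = 0.0515), in a fit of E+3P and E2 alone (0.13), with the smooth muscle covariate (-0.53, 0.0769), without the arrays that stand apart (-0.52, 0.114) and with 3 makeup covariates (-0.45, 0.139). Progestin response genes were higher, 8 of 26 called and 0 lower (10 and 1 over the list alone), with a median of 0.46 (adjusted p = 0.0031, and 0.217 with an estimated correlation). FOXO1, a transcription factor of the luteal phase endometrium, rose by 1.06 (adjusted p = 0.00241) and TSC22D3 by 0.98 (adjusted p = 0.000584).

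Lists of epithelial cell types shifted after 3 days, in step with the makeup of 2 arrays. In scaled median absolute deviations from the median of all arrays, the columnar epithelium list lay at -9.74 in E+3P replicate 2 and -4.69 in replicate 3, and the ciliated cell list at -5.55 and -5.38. Replicate 3 was also high in squamous epithelium genes (6.98). Mucin and mucus genes had 5 lower and 0 higher members of 24 (9 and 0 over the list alone) and a median of -0.61 (camera adjusted p = 0.00208, and 0.535 with an estimated correlation). The mucin shift was also lost with the smooth muscle covariate (median -0.34, adjusted p = 0.0758), without the arrays that stand apart (-0.19, 0.179) and with 3 makeup covariates (-0.0775, 0.267). Besides AGR2, they included SPDEF, a transcription factor of goblet cells, at -0.86 (adjusted p = 0.00845), and DMBT1, a mucosal scavenger protein, at -2.08 (adjusted p = 0.00532). Ciliated cell genes had 9 lower members of 27 (22 over the list alone), among them CAPS at -1.30 (adjusted p = 0.00218) and the cyclin gene CCNO of multiciliated cells at -0.56 (adjusted p = 0.0122). Their median was -1.30 (camera adjusted p = 2.37e-09, and 0.621 with an estimated correlation). Columnar epithelium genes had 5 lower and 1 higher members of 24 (8 and 1 over the list alone) and a median of -0.77 (adjusted p = 0.00203, and 0.674 with an estimated correlation). The shift was not called without E+3P replicate 2 (adjusted p = 0.117), with the smooth muscle covariate (-0.30, 0.21) or without the arrays that stand apart (-0.0146, 0.472), which were picked in part by this list. The 3 makeup covariates include the list's own mean, so the median of 0.0601 with them follows by construction. The tetraspanin gene TSPAN8 fell by 2.63 (adjusted p = 0.00244) and the gland transcription factor gene FOXA2 by 0.76 (adjusted p = 0.00813). Epithelial defence genes had 5 lower and 1 higher members of 27 (5 and 1 over the list alone), with LYZ, lysozyme, at -1.71 (adjusted p = 0.00778) and SLPI, a secreted protease inhibitor, at -2.18 (adjusted p = 0.00563), and the list was not called (adjusted p = 0.088). In a fit of E+3P and E2 alone SPDEF (adjusted p = 0.0555), DMBT1 (0.0654), CAPS (0.054), CCNO (0.103), FOXA2 (0.0633), LYZ (0.0926) and SLPI (0.0922) were not called. With 3 makeup covariates SPDEF (-0.71, adjusted p = 0.0624) and FOXA2 (-0.51, 0.0838) were not.

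Smooth muscle genes were higher after 3 days by a median of 1.05 with 0 of 20 members called (camera adjusted p = 0.000901, and 0.674 with an estimated correlation), and the shift was not called without the arrays that stand apart (adjusted p = 0.0762). The 3 makeup covariates include this list's own mean, so its median of 0.13 with them (adjusted p = 0.948) follows by construction. Endothelial genes had 3 higher members of 14 (4 over the list alone), among them the angiopoietin receptor gene TEK at 0.90 (adjusted p = 0.0091) and VWF, von Willebrand factor, at 0.68 (adjusted p = 0.0227), with a median of 0.37 (adjusted p = 0.00977, and 0.674 with an estimated correlation). Leaving out E+3P replicate 2 ended the endothelial call (adjusted p = 0.124), as did the smooth muscle covariate (0.122), leaving out the arrays that stand apart (0.242) and 3 makeup covariates (0.491), and leaving out that array or E2 replicate 4 ended the VWF call (highest adjusted p = 0.0565). Matrix remodelling genes went both ways, 4 higher and 2 lower of 27 (5 and 2 over the list alone). TIMP1, a metalloproteinase inhibitor, fell by 1.07 (adjusted p = 0.0182, and 0.05 without E2 replicate 5). Cell junction genes had 3 higher and 3 lower members of 27 (3 and 4 over the list alone), with the gap junction gene GJA1 at -1.27 (adjusted p = 0.0134). Of 32 ion and water transport genes 2 were higher and 3 lower (2 and 4 over the list alone), with the chloride channel gene ANO1 at -1.21 (adjusted p = 0.00917, and 0.0958 without the arrays that stand apart). In a fit of E+3P and E2 alone TEK (adjusted p = 0.0811), VWF (0.135), TIMP1 (0.116), GJA1 (0.133) and ANO1 (0.0899) were not called. With 3 makeup covariates VWF (0.47, adjusted p = 0.115) and TIMP1 (-1.04, 0.0633) were not, and VWF was also lost with array weights (0.0557), with the smooth muscle covariate (0.0565) and without the arrays that stand apart (0.144).

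In limma, 4214 probe sets differed between E+3P and E2, 2051 higher and 2163 lower, and 676 by at least 2-fold (160 higher, 516 lower). They belonged to 1895 genes, 782 higher and 1113 lower. With each array centred on its median the split was 1351 higher and 2717 lower. In a fit of E+3P and E2 alone 825 were called. The count was 2232 without the 4 arrays that stand apart, of which 1848 were shared in the same direction, and 2402 with 3 makeup covariates. It fell to 2592 without E+3P replicate 2, to 2699 without E2 replicate 2 and to 2809 without E2 replicate 5.

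**Figure D3:**
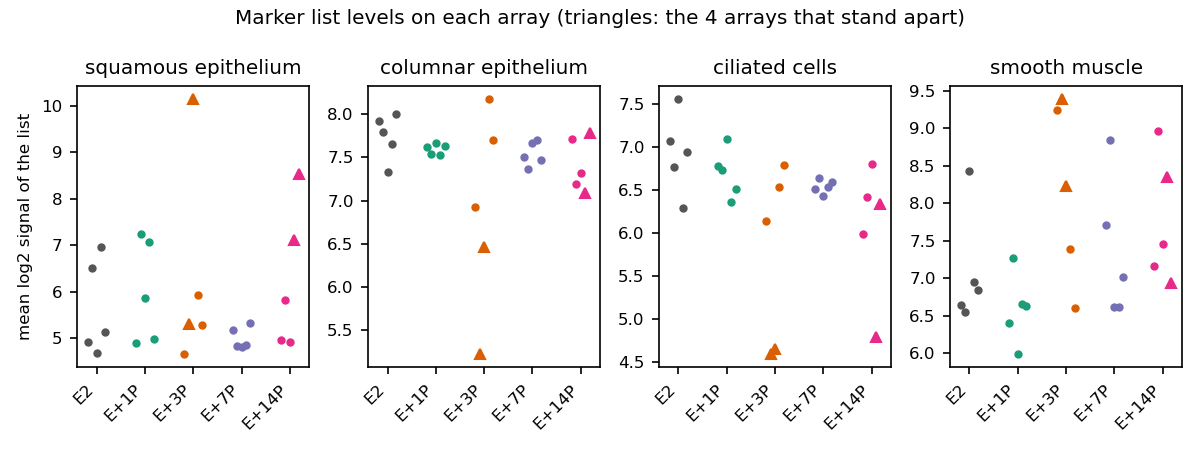
Mean log2 signals of 4 marker lists are plotted for each array by group, with triangles for the arrays that lie over 4 scaled median absolute deviations from the median in the squamous, columnar or ciliated list. E+3P replicate 2 has the lowest columnar mean at 5.22 and E+3P replicate 3 the highest squamous mean at 10.15.

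The comparison of E+7P with E2 describes the cervix after a week of progesterone. The mucus protein gene CLCA1 (probe set 13584945) fell from 10.63 ± 1.30 to 5.72 ± 1.03 (n = 5 per group), a change of -4.91 (SE 0.78, adjusted p = 0.000788), with all 5 E+7P arrays below every E2 array. OVGP1 fell to 5.14 ± 0.32, a change of -4.19 (SE 0.74, adjusted p = 0.00194), while CHI3L1 fell by 2.78 (SE 0.44, adjusted p = 0.000752) and DIO2 by 2.45 (SE 0.32, adjusted p = 0.000133). The carbonic anhydrase related gene CA10 dropped by 2.30 (adjusted p = 0.00115), the paraoxonase gene PON3 by 2.26 (adjusted p = 0.0142) and GRIA2 by 2.23 (adjusted p = 0.000718). CCDC141 rose by 2.50 (SE 0.33, adjusted p = 0.000141), TNFSF10 by 2.40 (SE 0.31, adjusted p = 0.000111), GPX3 by 2.25 (adjusted p = 0.00295) and PDK4 by 2.33 (adjusted p = 0.0119). MME and ALDH1A3 were higher by 2.18 (adjusted p = 0.0013) and 2.11 (adjusted p = 0.000718). CCL26, a chemokine for eosinophils, had the largest rise at 3.80 (SE 1.02, adjusted p = 0.0337), with all 5 E+7P arrays above every E2 array. Its call was lost without any of the 5 E+7P arrays or E2 replicate 2, 4 or 5 (highest adjusted p = 0.0939). That of TFCP2L1, an epithelial transcription factor (1.82, adjusted p = 0.0224), was lost without E+7P replicate 3 or 5 or E2 replicate 2 or 5 (highest adjusted p = 0.0606).

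Endoplasmic reticulum folding and secretion genes were lower by a median of -0.69 after 7 days, with 19 of 27 members called and 0 higher (21 and 0 over the list alone). The camera adjusted p was 6.78e-22, and 0.0062 with an estimated correlation. PDIA6 fell by 1.02 (SE 0.13, adjusted p = 9.48e-05), MANF by 1.23 (adjusted p = 0.000442), SEC61B by 0.95 (adjusted p = 0.000378) and DNAJC3 by 0.87 (adjusted p = 0.000158), each with all 5 E+7P arrays below every E2 array. Estrogen response genes had 4 lower and 0 higher of 18 (6 and 2 over the list alone), a median of -0.62 and adjusted p values of 0.00232 and, with an estimated correlation, 0.0153. Besides OVGP1 they were PGR at -1.17 (adjusted p = 0.00157), CCND1, cyclin D1, at -0.76 (adjusted p = 0.00305), and NRIP1 at -0.65 (adjusted p = 0.0204), the last not called without E+7P replicate 3 or E2 replicate 1 or 4 (highest adjusted p = 0.0536). Progestin response genes had 7 higher and 0 lower of 26 (8 and 0 over the list alone), a median of 0.46 and adjusted p values of 1.71e-06 and, with an estimated correlation, 0.0136. FKBP5 was 1.496 higher (adjusted p = 0.000356), IL1R1, the interleukin 1 receptor, 1.55 higher (adjusted p = 0.00111), TSC22D3 0.94 higher (adjusted p = 0.0011) and FOXO1 0.92 higher (adjusted p = 0.00811).

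Mucin and mucus genes had 3 lower and 0 higher members of 24 after 7 days (5 and 0 over the list alone) and a median of -0.38 (camera adjusted p = 0.0052, and 0.653 with an estimated correlation), with SPDEF at -1.04 (adjusted p = 0.00304) and DMBT1 at -2.09 (adjusted p = 0.00654). Among 27 epithelial defence genes 3 were lower and 0 higher, with the same counts over the list alone: CHI3L1, DMBT1 and LYZ, the last by -1.98 (adjusted p = 0.00364). The list was not called (adjusted p = 0.405). Ciliated cell genes had 2 lower members of 27 (2 over the list alone) and a median of -0.41 (adjusted p = 0.00846, and 0.977 with an estimated correlation). That shift was not called without E2 replicate 3 (adjusted p = 0.151), which had the highest ciliated mean of all arrays at 7.56, or with dim probe sets left out (0.053). T and natural killer cell genes were 0.40 higher at the median with 0 of 23 members called (adjusted p = 0.00459, 0.053 with dim probe sets left out and 0.977 with an estimated correlation). Columnar epithelium genes, with 1 lower member of 24 (CLDN10 at -2.15, adjusted p = 0.00996), were not called as a list (adjusted p = 0.644). In the matrix remodelling list 2 of 27 members rose and 2 fell (4 and 2 over the list alone). TIMP2, a metalloproteinase inhibitor, rose by 1.07 (adjusted p = 0.0192, and up to 0.0512 without E+7P replicate 2 or 4).

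In limma, 1695 probe sets differed between E+7P and E2, 739 higher and 956 lower, and 301 by at least 2-fold (133 higher, 168 lower). They belonged to 909 genes, 353 higher and 556 lower. Centring the arrays gave 532 higher and 1172 lower. The count was 2241 without the arrays that stand apart, with 1635 shared in the same direction, 1008 without E+7P replicate 5 and 1064 without E2 replicate 4.

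**Figure D4:**
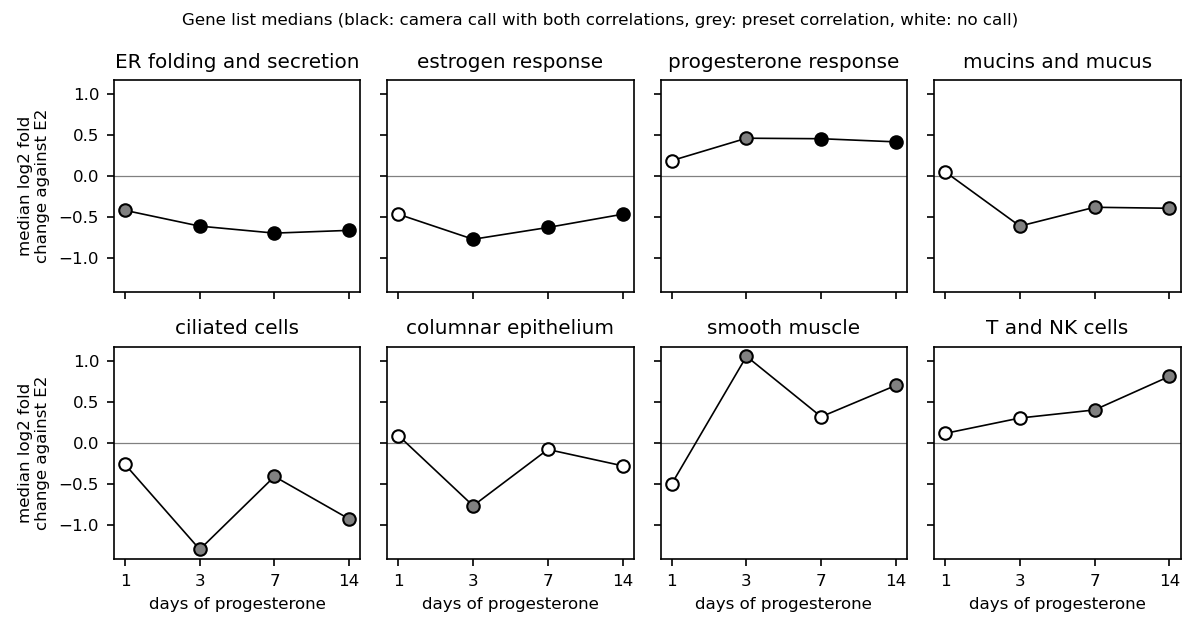
Median log2 fold changes against E2 are plotted for 8 gene lists by days of progesterone, with black points where camera made a call with both correlations, grey where it did so with the preset correlation alone and white where it made none. The endoplasmic reticulum list runs from -0.42 after 1 day to -0.69 after 7 days, and the T and natural killer cell list from 0.12 to 0.81 after 14 days.

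The comparison of E+14P with E2 describes the cervix after 14 days of progesterone. OVGP1 (probe set 13598065) fell by 4.47 (SE 0.74, adjusted p = 0.00123), from 9.33 ± 2.20 to 4.87 ± 1.11 (n = 5 per group), with all 5 E+14P arrays below every E2 array. CLCA1 decreased by 3.79 (SE 0.78, adjusted p = 0.00691), while CHI3L1 fell by 3.12 (SE 0.44, adjusted p = 0.000318) and CLDN10 by 2.87 (SE 0.47, adjusted p = 0.00117). ECRG4, a secreted hormone-like peptide gene, dropped by 2.74 (SE 0.42, adjusted p = 0.000593), DIO2 by 2.66 (adjusted p = 6.61e-05) and DKK2 by 2.82 (adjusted p = 0.0119, and 0.0766 in a fit of E+14P and E2 alone). SYT10 dropped by 2.85 (adjusted p = 0.0169), a call lost without E+14P replicate 4 (adjusted p = 0.0588). CCDC141 rose by 2.98 (SE 0.33, adjusted p = 5.09e-05) and GPX3 by 2.48 (SE 0.42, adjusted p = 0.00144). ALDH1A3 was 2.27 higher (SE 0.33, adjusted p = 0.00038), TNFSF10 2.23 higher (adjusted p = 0.000229) and TTN 2.14 higher (adjusted p = 0.00152). The matrix protein gene ABI3BP rose by 2.11 (adjusted p = 0.00217), and MASP1, a protease of the lectin complement pathway, by 2.04 (adjusted p = 0.000461). SERPINA3, an acute phase protease inhibitor, had the largest rise at 3.31 (SE 0.92, adjusted p = 0.0445), lost without E+14P replicate 1, 2, 4 or 5 or E2 replicate 1, 2, 4 or 5 (highest adjusted p = 0.122). The gene is in the estrogen response list and was 3.08-, 6.77- and 8.64-fold higher after 1, 3 and 7 days, without a call.

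Endoplasmic reticulum folding and secretion genes stayed below E2 after 14 days, with 16 of 27 members called lower and 0 higher (21 and 1 over the list alone) and a median of -0.66. The camera adjusted p was 5.44e-18, and 0.0167 with an estimated correlation, and PDIA6 was 0.82 lower, a change of -0.82 (adjusted p = 0.000655). Estrogen response genes had 4 lower and 1 higher of 18 (8 and 3 over the list alone), a median of -0.46 and adjusted p values of 0.00238 and, with an estimated correlation, 0.0211. The higher member was SERPINA3. CCND1 fell by 1.17 (SE 0.14, adjusted p = 7.5e-05). PGR fell by 0.76 (adjusted p = 0.0354), a call lost without E+14P replicate 1, 4 or 5 or E2 replicate 1, 2, 4 or 5 (highest adjusted p = 0.0941) and without the arrays that stand apart (0.138). Progestin response genes had 7 higher and 0 lower of 26 (7 and 0 over the list alone), a median of 0.42 and adjusted p values of 9.81e-06 and, with an estimated correlation, 0.0211. FOXO1 was 1.14 higher (adjusted p = 0.00164), IL1R1 1.27 higher (adjusted p = 0.00571) and FKBP5 1.58 higher (adjusted p = 0.000206). JUN, of the immediate early list, was 1.99 higher (adjusted p = 6.61e-05), and 1 member of that list was lower.

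T and natural killer cell genes were higher by a median of 0.81 after 14 days, with 3 of 23 members called and 0 lower (14 and 0 over the list alone). The camera adjusted p was 1.29e-08, and 0.332 with an estimated correlation. IL2RB, an interleukin 2 receptor chain, rose by 0.89 (adjusted p = 0.0124), and the granule protein gene NKG7 by 1.16 (adjusted p = 0.0236), the latter not called without E+14P replicate 1 or 4 or E2 replicate 3 or 4 (highest adjusted p = 0.0722). UBASH3A, a T cell signalling gene, rose by 0.95 (adjusted p = 0.0107, but 0.1 without the arrays that stand apart and 0.0649 in a fit of E+14P and E2 alone). This gene was 1.88-, 1.84- and 1.65-fold higher than in E2 after 1, 3 and 7 days already, against 1.94-fold after 14 days. The list median after 1 day was 0.12, so UBASH3A did not follow the later rise of the list. The list mean was highest in E+14P replicate 4 at 6.65, an array that also lay at -4.96 scaled median absolute deviations in the ciliated list. Ciliated cell genes had 3 lower members of 27 (4 over the list alone) and a median of -0.93 (adjusted p = 3.24e-08, and 0.644 with an estimated correlation), with CCNO at -0.83 (adjusted p = 0.00104) and CAPS at -1.08 (adjusted p = 0.0108). Mucin and mucus genes had 3 lower members of 24 (5 lower and 2 higher over the list alone) and a median of -0.39 (adjusted p = 0.0069, 0.0975 with the smooth muscle covariate and 0.594 with an estimated correlation). Smooth muscle genes were 0.70 higher at the median with 0 of 20 called (adjusted p = 0.0112, and 0.886 with an estimated correlation), a call lost without E+14P replicate 2 or 4 or E2 replicate 1 or 2 (highest adjusted p = 0.274). E2 replicate 3 had a smooth muscle mean of 8.43, against 6.55 to 6.95 on the other E2 arrays. TIMP2 rose by 1.10 (adjusted p = 0.018), not called without E+14P replicate 4 (adjusted p = 0.0531) or without the arrays that stand apart (0.0751).

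In limma, 1528 probe sets differed between E+14P and E2, 600 higher and 928 lower, and 339 by at least 2-fold (142 higher, 197 lower). They belonged to 900 genes, 351 higher and 549 lower. Centring the arrays gave 456 higher and 1049 lower. The count was 837 without the 4 arrays that stand apart, 2 of which are in this group, with 697 shared in the same direction, 862 without E+14P replicate 4 and 940 without E2 replicate 4. The animals of E+14P carry numbers from 1263 to 1798, below those of every other array except E+7P replicate 1 (1568), and those of E+3P run from 1875 to 1881. The labels give no batch, and if the numbers mark cohorts, cohort and group cannot be separated for these groups.

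Of the 27 lists, 18 had no called shift against E2 at any of the 4 times. The largest evidence among them was for 29 collagen and matrix genes after 1 day (median -0.27, camera adjusted p = 0.0686), where VCAN was the 1 called member, and for 20 interferon genes on the same day (-0.20, 0.0686). Fat, nerve and skeletal muscle genes (14 measured) had their lowest adjusted p after 3 days (0.51, 0.0715), as did epithelial defence genes (-0.25, 0.088), 15 immediate early genes (0.22, 0.158), 25 squamous epithelium genes (0.75, 0.164), cell junction genes (-0.11, 0.22), 5 blood genes (0.22, 0.297) and 8 mast cell genes (-0.14, 0.432). After 14 days the lowest values were those of 21 myeloid genes (0.38, 0.114), 13 B and plasma cell genes (0.16, 0.133), matrix remodelling genes (0.18, 0.184), 23 cell cycle genes (-0.13, 0.198) and 17 prostaglandin genes (-0.15, 0.386). Cytokine and chemokine genes (35 measured) had theirs after 1 day (-0.05, 0.228), as did 15 endometrial markers (-0.14, 0.587), and 13 neutrophil genes (-0.20, 0.474) and ion and water transport genes (0.12, 0.644) after 7 days. Of the lists called against E2, those that hold with an estimated correlation were the endoplasmic reticulum and estrogen response lists after 3, 7 and 14 days and the progestin response list after 7 and 14 days. Median, mean and test differed in sign for the ion transport, cell cycle, columnar, endothelial, B and plasma cell, neutrophil, cytokine, defence, interferon, junction, fat and nerve, and endometrial lists in at least 1 comparison with E2, none of them called there.

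The comparisons of consecutive times ask when the changes set in. Between E+1P and E+3P, KRT222 dropped by 3.56 (SE 0.31, adjusted p = 4.3e-07), and HGD by 2.14 (SE 0.24, adjusted p = 1.46e-05), back to 4.12 ± 0.42 and 4.70 ± 0.33 (n = 5 per group) against E2 signals of 4.84 ± 0.34 and 4.53 ± 0.21. OVGP1 dropped by 3.27 (SE 0.74, adjusted p = 0.014), the MIR147B probe set by 3.21 (adjusted p = 7.07e-05), ST6GALNAC1 by 2.93 (adjusted p = 0.00264) and SPDEF by 1.51 (adjusted p = 6.93e-05). BTG2 fell by 1.54 (adjusted p = 3.92e-05), CCND1 by 0.87 (adjusted p = 0.000852) and the phospholipase gene PLA2G4A by 1.43 (adjusted p = 0.00409), while FOXO1 rose by 0.93 (adjusted p = 0.00866) and TNFSF10 by 1.36 (adjusted p = 0.0139). Of these, OVGP1 and PLA2G4A were not called without the arrays that stand apart (adjusted p = 0.138 and 0.0803) or with 3 makeup covariates (0.0632 and 0.084), and with the smooth muscle covariate these 2 genes (0.0607 and 0.104), ST6GALNAC1 (0.0689) and FOXO1 (0.167) were not. In these 3 settings, in that order, the OVGP1 change was -2.78, -3.42 and -3.50, and that of PLA2G4A -1.11, -0.86 and -0.88. In a fit of the compared groups alone PLA2G4A (0.0739), ST6GALNAC1 (0.0602) and TNFSF10 (0.0696) were not called. The largest rises were in PTGIS, prostacyclin synthase (2.62, adjusted p = 0.0396), PGM5, a muscle phosphoglucomutase-like gene (2.57, adjusted p = 0.049), ABCC9, a potassium channel regulator of muscle (2.05, adjusted p = 0.02), and TCEAL3 (1.86, adjusted p = 0.0153), and none of these 4 was called without the arrays that stand apart (adjusted p 0.131 to 0.261). Leaving out E+3P replicate 2 ended all 4 calls, leaving out E+3P replicate 1 those of PTGIS, PGM5 and ABCC9, and leaving out E+3P replicate 3 or E+1P replicate 1, 4 or 5 those of PTGIS and PGM5, with highest adjusted p values of 0.132, 0.146, 0.0712 and 0.055 in the order given. E+1P replicate 3 was needed for PTGIS, PGM5 and ABCC9. None of the 4 was called in a fit of the compared groups alone (adjusted p 0.0676 to 0.114), with the smooth muscle covariate (0.187 to 0.476) or with 3 makeup covariates (0.175 to 0.4).

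Smooth muscle genes were 1.57 higher at the median in E+3P than in E+1P, with 4 of 20 members called (19 over the list alone), among them LMOD1, leiomodin, at 1.74 (adjusted p = 0.046), not called without E+3P replicate 1, 2 or 3 or any of the 5 E+1P arrays (highest adjusted p = 0.149), without the arrays that stand apart (0.292), in a fit of the compared groups alone (0.129) or with the smooth muscle (0.412) or 3 makeup covariates (0.334). Those covariates include the mean of the smooth muscle list, to which LMOD1 belongs. The camera adjusted p was 2.38e-08, and 0.508 with an estimated correlation. Mucin and mucus genes had 6 lower members of 24 (10 over the list alone), a median of -0.81 and adjusted p values of 6.33e-05 and, with an estimated correlation, 0.376. Of 27 lists 11 shifted between these days, 5 up and 6 down, and 0 of these calls held with an estimated correlation. In limma, 1790 probe sets differed, 570 higher and 1220 lower (400 and 1534 with centred arrays), in 915 genes. In a fit of the compared groups alone 369 were called, and 431 with the smooth muscle covariate. The count was 547 without the arrays that stand apart, of which 470 were shared in the same direction. It was 929, 842, 1061 and 1192 without E+1P replicates 1, 3, 4 and 5, 1180 and 879 without E+3P replicates 1 and 2, and 3665 without E+3P replicate 5.

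Between E+3P and E+7P limma called 2 probe sets, both higher, with 4512 at an unadjusted p under 0.05. The named gene was PLEKHA5, a membrane adaptor gene, which was 0.71 higher (SE 0.11, adjusted p = 0.04). Each of E+3P replicates 1 to 4 and E+7P replicates 1 to 5 was needed for this call (highest adjusted p = 0.153 without 1 of them). The call was also lost with quantile normalization (0.0652), no variance trend (0.0719), array weights (0.057), the squamous (0.0708), smooth muscle (0.164) and 3 makeup covariates (0.2), without the arrays that stand apart (0.425) and in a fit of the compared groups alone (0.607). The PLEKHA5 change itself lay between 0.68 and 0.75 in these settings. The count was 65 without E+3P replicate 5, 4 without E+3P replicate 1, 1 without E+3P replicate 4 or E+7P replicate 1, 4 or 5, and 0 without replicate 2 or 3 of either group. Between E+7P and E+14P limma called 0 probe sets, with 1729 at an unadjusted p under 0.05. In both comparisons 6 of 27 lists were called and 0 held with an estimated correlation. T and natural killer cell genes were 0.32 higher after 14 days than after 7 (adjusted p = 2.37e-06, and 0.921 with an estimated correlation).

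Across the 4 comparisons with E2, limma's F test called 3590 probe sets in 1863 genes. Of the probe sets, 842 changed most after 1 day, 1391 after 3 days, 715 after 7 days and 642 after 14 days, and 2286 had the same sign at all 4 times. The calls overlapped in direction: 371 probe sets were higher and 748 lower after both 3 and 7 days, where 37.4 and 51.1 would be shared if the calls were independent, and 0 went opposite ways. After both 7 and 14 days 330 were higher and 604 lower, against 10.95 and 21.9, and 0 went opposite ways. After both 1 and 3 days 137 were higher and 230 lower, against 28.5 and 20.1, and 10 went opposite ways. After both 1 and 14 days 104 were higher and 161 lower, against 8.3 and 8.6, and 7 went opposite ways. The comparisons share the E2 arrays, which raises such overlap. In 20 simulations with shared E2 arrays and no changes, the changes at 2 times correlated across probe sets at a mean Pearson's r of 0.50. The measured r was 0.68 for 3 and 7 days and 0.74 for 7 and 14 days, 0.43 for 1 and 3 days and 0.41 for 1 and 14 days. The covariances for these 4 pairs were 0.0941, 0.0895, 0.0584 and 0.0485, against simulated means of 0.0307 to 0.0308. The simulated probe sets were drawn independently, whereas real genes move together, for example with tissue makeup. These simulations thus cannot show how far r or the covariance varies without hormone changes, and the excess covariance decides nothing about a shared effect. With the E2 arrays divided so that the comparisons share none, the mean r was 0.39, 0.40, 0.18 and 0.14. Probe sets are not independent replicates.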

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

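The test of plasma cells, the omission of single day 3 arrays and of pairs of them, the 3 makeup covariates together and the omission of the arrays that stand apart were chosen only after the result they bear on was seen.

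A single array lay far from the other 4 of its group for some of the genes and lists given in the text. By Dixon's ratio of the gap to the range, 41 of 480 groups (8.54%) exceeded the critical value of 0.71, where chance gives about 1 in 20 groups. E2 replicate 3 accounted for 13 of the 39 cases in genes. It was highest for ABCC9 (0.786), MANF (0.794), PDK4 (0.741), PGM5 (0.773) and PTGIS (0.853), and lowest for CA10 (0.76), CCND1 (0.765), CITED1 (0.941), IL33 (0.965), SEMA3D (0.887), SLPI (0.848), STC1 (0.782) and TIMP1 (0.751). It was also highest in the smooth muscle list (0.791), with a mean log2 signal of 8.43. Its means in the progestin response list (6.59) and the estrogen response list (8.16) lay near those of the other E2 arrays, 6.68 to 6.80 and 7.97 to 8.32. Without this array 965 probe sets were called after 1 day, 3690 after 3 days, 1696 after 7 days and 1493 after 14 days.

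Other arrays stood out for fewer of the genes. In E+1P, replicate 4 was lowest for AGR2 (0.735) and DUSP1 (0.714) and highest for GJA1 (0.855), and replicate 5 was lowest for FKBP5 (0.724). In E+3P, replicate 3 was lowest for ECRG4 (0.73) and highest in the squamous epithelium list (0.769), replicate 2 was lowest for MME (0.735), replicate 5 highest for TSC22D3 (0.714) and replicate 1 highest for TTN (0.767). In E+7P, replicate 4 was highest for AOX1 (0.719) and CCND1 (0.814), replicate 2 for TCEAL3 (0.727) and TTN (0.711), replicate 3 for NKG7 (0.727) and replicate 1 for PLEKHA5 (0.762), and replicate 5 was lowest for PDIA6 (0.718). In E+14P, replicate 1 was highest for CHI3L1 (0.845), OVGP1 (0.859), SERPINA3 (0.73) and TMED3 (0.725), and replicate 3 for IL1R1 (0.79). Replicate 2 of that group was lowest for DUSP1 (0.782) and TEK (0.726), replicate 4 for IL33 (0.823) and SYT10 (0.712), and replicate 5 for LMAN1 (0.783). In E2, replicate 5 was lowest for TTN (0.72).

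The effects of 1 and 3 days of progesterone differed, by limma's direct comparison of E+3P with E+1P, for 35 genes given in the text. Lower after 3 days were KRT222 (-3.56), OVGP1 (-3.27), MIR147B (-3.21), ST6GALNAC1 (-2.93), MUC15 (-2.81), SYT10 (-2.38), TSPAN8 (-2.33, with 5 of 5 E+3P arrays below every E2 array), HGD (-2.14), SLPI (-1.86), STRA6 (-1.84), MME (-1.70), ECRG4 (-1.68), RGCC (-1.65), LYZ (-1.54), BTG2 (-1.54), SPDEF (-1.51) and PLA2G4A (-1.43). Smaller falls were those of TMED3 (-1.04), CAPS (-0.87), CCND1 (-0.87), LMAN1 (-0.77), NDUFB5 (-0.73), ALG14 (-0.72), NDUFB3 (-0.56), MAGT1 (-0.52), DNAJC3 (-0.42) and PLEKHA5 (-0.41). Higher after 3 days were PTGIS (2.62), PGM5 (2.57), ABCC9 (2.05), TCEAL3 (1.86), LMOD1 (1.74), TNFSF10 (1.36), FOXO1 (0.93) and KLF7 (0.88). For 18 of these genes the difference held in each test with an array left out, and for the other 17 it did not (highest adjusted p = 0.149). Of the 35 calls, 17 were lost without the arrays that stand apart, 21 with the smooth muscle covariate, 18 with 3 makeup covariates and 21 in a fit of the compared groups alone. In all settings other than the omission of 1 array 24 were lost in at least 1, and KRT222, MIR147B, HGD, STRA6, BTG2, SPDEF, TMED3, CCND1, LMAN1, NDUFB5 and ALG14 were kept. Without the arrays that stand apart SLPI changed by -0.91 (adjusted p = 0.174), SYT10 by -0.97 (0.11) and RGCC by -0.9996 (0.235), and CAPS (0.171), ECRG4 (0.115), MUC15 (0.0619), MME (0.065) and KLF7 (0.249) were also lost. With 3 makeup covariates LYZ changed by -0.75 (0.156), TSPAN8 by -1.36 (0.106) and KLF7 by 0.27 (0.419). Some lost calls kept most of their change with these covariates, among them OVGP1 at -3.42 (0.0632), MME at -1.53 (0.0967), ECRG4 at -1.46 (0.142) and DNAJC3 at -0.47 (0.105). A lost call is thus not always a smaller change. Between 3 and 7 days PLEKHA5 differed (0.71).

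Between 1 and 3 days the median of the list differed for smooth muscle (1.57), ciliated cell (-0.90), mucin (-0.81), columnar epithelium (-0.57), estrogen response (-0.47), endothelial (0.38), collagen and matrix (0.37), interferon (0.34), endoplasmic reticulum (-0.26), matrix remodelling (0.25) and cell junction genes (-0.23). Between 3 and 7 days it differed for squamous epithelium (-1.28), ciliated cell (0.87), smooth muscle (-0.79), columnar epithelium (0.65), myeloid (0.45) and fat, nerve and skeletal muscle genes (-0.37). From 7 to 14 days it differed for squamous epithelium (0.92), ciliated cell (-0.50), smooth muscle (0.40), T and natural killer cell (0.32), collagen and matrix (0.27) and immediate early genes (-0.14). The calls are by camera, and with an estimated correlation 0 of the 23 were made. Without the arrays that stand apart 7 of 11 were lost between 1 and 3 days, 5 of 6 between 3 and 7 days and 2 of 6 between 7 and 14 days. With 3 makeup covariates 6, 5 and 3 were lost. They included smooth muscle genes at each step, columnar genes up to 7 days and squamous genes from 3 days on. The means of these lists are the covariates, so those losses follow by construction. Between 1 and 3 days collagen and matrix genes turned to a called fall, with a median of -0.19 with the smooth muscle covariate (adjusted p = 0.0334) and -0.22 with the 3 covariates (0.0259). With the same covariates cell junction genes turned without a call, as did smooth muscle genes, whose own mean was in both fits. The lowest adjusted p with an estimated correlation was 0.376 between 1 and 3 days, 0.74 between 3 and 7 days and 0.921 between 7 and 14 days. Without E+3P replicate 2 the columnar (0.0647), endothelial (0.0678) and estrogen response shifts between 1 and 3 days were not called, nor were the columnar (0.188) and fat, nerve and skeletal muscle shifts (0.576) between 3 and 7 days, with the adjusted p in brackets (estrogen response, up to 0.0719 without this array or E+1P replicate 2). Without E+3P replicate 3 the squamous shift between 3 and 7 days was not called (0.602), nor the interferon shift between 1 and 3 days (0.0706). E+1P replicate 3 and E+3P replicates 1 and 2 were each needed for the cell junction (highest 0.429) and collagen shifts (0.169) between 1 and 3 days, E+3P replicate 4 for the matrix remodelling shift (0.0603) and E+3P replicate 5 for the myeloid shift (0.11). Between 7 and 14 days the ciliated shift was not called without E+14P replicate 4 (0.106). That array, E+14P replicate 2 and E+7P replicates 3 and 5 were each needed for the collagen (0.458) and smooth muscle shifts (0.671), the latter also lost without E+7P replicate 4, and E+7P replicates 1 and 2 and E+14P replicates 2 and 3 for the immediate early shift (0.19).

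More probe sets were called after 3 days than after 1, 7 or 14 days in the fit of all 25 arrays. The excess depends on the spread that the fit shares between groups: in fits of the compared groups alone the counts were 1320, 825, 1612 and 924 after 1, 3, 7 and 14 days, the lowest after 3 days. The columnar list mean had an SD of 1.147 in E+3P and of 0.058 to 0.314 in the other groups. The pooled spread can thus understate that of the E+3P animals and make the day 3 p values too small. The ratio of the day 3 to the day 7 count was 2.49 with all arrays and 0.989 with 3 makeup covariates, so tissue makeup may account for the excess. Without the 4 arrays that stand apart in epithelial makeup, E+3P replicates 2 and 3 and E+14P replicates 4 and 5, the ratio was 0.996. With the same 2 E+14P arrays left out, 3 of the 9 other pairs of day 3 arrays also gave a ratio at or under 1.5, from a range of 1.03 to 2.58, and those 3 all include replicate 2. Without E+3P replicate 2 alone the ratio was 1.35, the lowest for any single array, so this array may account for most of the excess. Without replicate 3 alone it was 1.94, against 2.15 to 2.63 without replicate 1, 4 or 5, which argues against replicate 3 as the whole cause. The epithelial makeup itself could be an effect of progesterone or of where each piece of cervix was taken, which the labels do not give.

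Endoplasmic reticulum folding and secretion genes were lower after 7 days. Fewer columnar cells would be expected to remove the shift when makeup is in the model, and the median was -0.66 with the 3 covariates. The columnar mean, however, differed little between E2 (7.74, SD 0.26) and E+7P (7.54, SD 0.14). This covariate could therefore take away little of the shift, and the fit cannot decide the question. The columnar list itself was not called lower after 7 days (median -0.08, camera adjusted p = 0.644). A loss of secretory cells alone was not tested. Fewer plasma cells might lower such genes, and JCHAIN, an abundant plasma cell gene, changed by -0.93 (SE 0.91, adjusted p = 0.666). With the JCHAIN signal as a covariate, which was associated with 51 probe sets, the median was -0.66 (adjusted p = 1.55e-21, and 0.00251 with an estimated correlation). The shift thus did not follow JCHAIN, but 1 transcript may track plasma cells poorly, so this fit does not settle the question. The B and plasma cell list had a median of 0.036 after 7 days (camera adjusted p = 0.782). After 14 days JCHAIN was 3.20-fold higher than in E2, without a call, while the secretion list had a median of -0.66. Genes of transport from the endoplasmic reticulum and of N-glycosylation, from lists written before their values were seen, were lower too (higher of the 2 adjusted p values 3.01e-17), whereas targets of the PERK stress arm had a median of -0.065. The means of the list on the E+7P arrays (7.996 to 8.176) all lay below those on the E2 arrays (8.67 to 8.82). A candidate explanation is a lower demand for secretion under progesterone, as a hypothesis.

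Genes that rose after 1 day and were lower again after 3 days could reflect the makeup of the day 3 arrays. In that case they would be high again after 7 days, but the ratio of their median change at day 7 to that at day 1 was 0.0452. No biological explanation was tested.

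Splits of the arrays into random groups were used to ask whether chance can be excluded, with 100 splits per comparison, the real one included. Against E2, the real counts of 938, 1695 and 1528 after 1, 7 and 14 days were each reached by 1 split, the real one, and the highest other counts were 15, 43 and 192. After 3 days the count of 4214 was also reached by the real split alone, with a highest other of 814, and the F test's 3590 likewise, with a highest other of 168. Between 1 and 3 days 1790 was reached by the real split alone, but the highest other count was 1293. A random division of the arrays is thus an unlikely source of these counts, although 1 of 100 is the lowest share that 100 splits can give. The splits cannot tell progesterone from cohort or from other differences between the groups of animals. Between 3 and 7 days 4 splits gave at least the real count of 2, and 1 gave 1032. What divides the arrays in that split was not tested. Between 7 and 14 days the real count was 0 by limma, with 1729 at an unadjusted p under 0.05, and the highest other was 2. All 100 splits reach a count of 0 by necessity, so the splits decide nothing there.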

How the results depend on the processing

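The omission of the arrays that stand apart, the 3 makeup covariates and the omission of the first unnamed rows were chosen after seeing the data. The cause was not tested for any of the changes below, and signal over background is not known for these arrays.

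Counts moved by more than 1.5 times in these cases. With array weights 1986 probe sets were called after 1 day and 2832 after 7 days. A fit of the compared groups alone gave 825 after 3 days, 924 after 14 days and 369 between 1 and 3 days. With 1 probe set per gene the counts were 2247 after 3 days and 1116 after 7 days, out of 15534 tested instead of 40489, so these lower counts are not a lower share. A minimum change of 1.5-fold gave 2022 after 3 days, 884 after 7 days, 881 after 14 days, 1100 between 1 and 3 days and 2136 in the F test. A smooth muscle covariate gave 431 between 1 and 3 days. Without the arrays that stand apart the counts were 2232 after 3 days, 837 after 14 days and 547 between 1 and 3 days, and with 3 makeup covariates 2402 after 3 days and 532 between 1 and 3 days. Between 3 and 7 days the count of 2 became 1 with quantile normalization and with no variance trend, 4 with dim probe sets left out, and 0 with array weights, the fit of the compared groups alone, the squamous covariate, the smooth muscle covariate, the 3 makeup covariates and without the arrays that stand apart. The number of called list shifts was 45 of 189 with the preset correlation and 8 with an estimated correlation.

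Leaving out each array in turn gave 633 to 965 probe sets after 1 day, 2592 to 5114 after 3 days, 1008 to 1696 after 7 days and 862 to 1493 after 14 days. It gave 842 to 3665 between 1 and 3 days, 0 to 65 between 3 and 7 days, 0 to 0 by limma between 7 and 14 days (1729 at an unadjusted p under 0.05 with all arrays), 2621 to 5033 in the F test and 41 to 54 called list shifts.

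The direction of a list's test reversed in 24 cases, 22 of them with a covariate for tissue makeup. Where the smooth muscle, squamous or columnar list reversed with a covariate, that covariate was or included the list's own mean. The shift is then removed by construction, so the medians with covariates given below for these lists are no evidence of a reversal. The reversed direction was itself called for collagen and matrix (highest adjusted p = 0.0334), for cell cycle (0.0168) and for squamous epithelium between 1 and 3 days (0.0153), and for no other list. With the smooth muscle covariate and with the 3 covariates, in that order, the medians were 0.0865 and 0.0421 for cell junctions, -0.19 and -0.217 for collagen and matrix and -0.0359 and -0.0391 for smooth muscle between 1 and 3 days. They were -0.231 and -0.212 for collagen and matrix after 3 days, 0.141 and 0.248 for collagen and matrix and 0.0185 and 0.0326 for smooth muscle between 3 and 7 days, and 0.00887 and 0.01999 for smooth muscle between 7 and 14 days. With the squamous covariate and with the 3 covariates they were -0.124 and -0.126 for cell cycle and -0.152 and -0.173 for squamous epithelium between 7 and 14 days. For smooth muscle after 3 days the median was 0.087 with the smooth muscle covariate. With the 3 covariates alone it was 0.0601 for columnar epithelium after 3 days, -0.0381 for smooth muscle after 14 days and 0.0158 for squamous epithelium between 3 and 7 days. For squamous epithelium between 1 and 3 days it was -0.642 without the arrays that stand apart, and leaving out each array in turn gave -0.626 (without E+3P replicate 3) to 0.812 (without E+3P replicate 1).

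Of the 644 comparisons of the genes given in the text, 254 were called, and 0 reversed under any alternative. With quantile normalization 3 of these calls were lost, with centring 1, without a variance trend 4, with array weights 6, with the fit of the compared groups alone 67, with the squamous covariate 3 (FOXA2 after 14 days, PLEKHA5 between 3 and 7 days and STRA6 after 7 days), with the smooth muscle covariate 28, without the arrays that stand apart 38 and with the 3 covariates 34. Over all omissions of 1 array, 294 of 2540 were lost. No paired analysis was possible because the labels pair no animals.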

Other observations

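The lists of endoplasmic reticulum transport, N-glycosylation, PERK targets and retinoid metabolism, the families of genes with shared symbol letters and the 12 genes named for them were chosen after the results above were seen.

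Genes of transport from the endoplasmic reticulum to the Golgi were lower after 7 days. TMED3, a cargo receptor, fell by 1.25 (SE 0.14, adjusted p = 4.94e-05) and LMAN1, a lectin that carries glycoproteins, by 0.77 (adjusted p = 0.000141), with 19 of 33 members lower and 0 higher and a median of -0.39 (camera adjusted p = 2.48e-22, and 0.000457 with an estimated correlation). N-glycosylation genes had 14 lower and 0 higher of 31 and a median of -0.41 (adjusted p = 3.01e-17, and 0.00044 with an estimated correlation), among them ALG14 at -1.23 (adjusted p = 4.94e-05) and MAGT1 at -0.86 (adjusted p = 0.000555). After 3 and 14 days 20 and 14 transport genes and 17 and 12 glycosylation genes were lower, with calls that held with an estimated correlation. Of 16 PERK and ATF4 targets 1 was higher and 0 lower after 7 days (adjusted p = 0.961).

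Among 185 families of genes whose symbols share letters, Krueppel-like factors (14 genes) were higher, 6 of them called after 3 days, 3 after 7 days and 3 after 14 days, with medians of 0.40, 0.37 and 0.28 (adjusted p with an estimated correlation 0.0317, 0.0266 and 0.0413). KLF7 was 1.17 higher after 7 days and KLF11 0.92 higher. Mitochondrial ribosomal genes were lower, with medians of -0.29, -0.26 and -0.21 for 34 large subunit genes and -0.34, -0.31 and -0.26 for 25 small subunit genes at the same times. Among subunit genes of respiratory complex I, 8 of 10 NDUFB genes were lower after 7 days, with a median of -0.50 (adjusted p = 0.0222 with an estimated correlation), among them NDUFB3 by -0.74 and NDUFB5 by -0.56. Of 10 NDUFA genes 5 were lower on that day, with a median of -0.46 (adjusted p = 0.0245 with an estimated correlation). After 3 days the NDUFB call was lost with an estimated correlation (adjusted p = 0.113). Other families were called with the preset correlation. The COX, PSMB, PSMD and POLR families were lower after 3, 7 and 14 days. With an estimated correlation POLR was still called after 3 and 7 days (adjusted p = 0.024 and 0.022) and PSMD after 7 days (0.035). COX and PSMB were called at none of these times with it. The CFAP family had 15 of 38 genes lower after 3 days (adjusted p = 1.67e-10, and 0.425 with an estimated correlation). The 135 OR genes, olfactory receptors, were higher after 3 days, with 10 called and a median of 0.16 (adjusted p = 0.00625, and 0.375 with an estimated correlation). The cause of these family shifts, and whether signal level plays a part, was not tested.

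A set of 261 probe sets in 144 genes was called higher after 1 day and lower again from 1 to 3 days. Their median log2 change against E2 was 1.06 after 1 day and 0.0477 and -0.0108 after 7 and 14 days, and 7 and 4 of them were called higher at those times. KRT222, HGD and BTG2 belong to this set. The selection raises the 1 day median by itself and requires the fall by 3 days, so the values at these 2 times are no evidence of a return. The opposite pattern was seen in 38 probe sets in 19 genes, selected likewise, with medians of -0.70 after 1 day and -0.12 and -0.13 after 7 and 14 days.

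Retinoid genes went both ways. ALDH1A3, DHRS3, a retinaldehyde reductase, at 1.66 (SE 0.21, adjusted p = 0.000103), and RARB, a retinoic acid receptor, at 1.36 (adjusted p = 0.00138) were higher after 7 days, but the list of 21 genes had 3 higher and 2 lower members and was not called at day 7 or 14 (lower adjusted p = 0.671). The lower members were RARA, another retinoic acid receptor, at -0.35 (adjusted p = 0.0443), and STRA6, a retinol transporter, at -0.77 (adjusted p = 0.0473). Leaving out any of 9 of the 10 arrays compared ended the RARA call (highest adjusted p = 0.115), and leaving out any of the 10 ended the STRA6 call (0.123). RARA was also lower after 1, 3 and 14 days, by -0.41, -0.43 and -0.44 (adjusted p = 0.0242, 0.00926 and 0.0121). In fits of the compared groups alone it was not called after 1, 3 or 7 days (0.0842, 0.0545 and 0.0586). STRA6 was 1.67 higher after 1 day (adjusted p = 1e-04) and changed by -0.16 after 3 days (0.669).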
